A study of Mus musculus with 6 samples.

How the data were processed

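Chromatin isolation by RNA purification (ChIRP) recovers the DNA that lies near a chosen RNA: cells are cross-linked, the RNA is captured with biotinylated antisense DNA probes, and the attached DNA is sequenced. Per the labels' protocols, the RNA was Meg3, a maternally expressed long noncoding RNA, and the cells were MIN6-4N, a mouse insulinoma line of pancreatic beta cell origin. The labels describe 2 stable clones, one carrying the empty pcDNA3.1 plasmid and one carrying the plasmid with Meg3, selected in G418 at 750 µg/ml and expanded at 500 µg/ml. Chromatin was fixed with 1% glutaraldehyde from 10000000 cells, and each clone gave 3 libraries, an input, a pull-down with odd-numbered probes and a pull-down with even-numbered probes. Reads were single-end and 50 bp long, per the labels. Each of the 6 groups has 1 library, so there is no replicate of any library and no value below has a spread between replicates.

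The analysis starts from 1 deposited list of genomic regions, whose name carries the code of the Meg3 clone and the word unique. The list has other columns than coordinates only as placeholders: the authors deposited n/a as the name of every region and 0 in both value columns, so 0 rows hold a height, a fold enrichment or a p-value. The coordinates are on mm9, per the submitters' processing notes. Neither the peak caller, its threshold, the use made of the input, odd-probe and even-probe libraries, nor the aligner is given in the sources used here. It is also not stated whether unique means that a region was not called in the vector clone or that only uniquely placed reads were used. The number of reads per library is unknown, so no interval for read depth is given, and libraries of the vector clone were not analysed here.

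Region starts were converted to count from 1. Width is end minus start as deposited. The 5 mitochondrial regions were kept apart from the 9005 nuclear ones. Before the data were examined, the planned tests were the distribution over chromosomes, position relative to genes, gene lists, sequence composition, similarity to the Meg3 transcript and spacing. No genome sequence or gene annotation of mm9 was used here, so the tests that need genes or sequence were not run and no gene is assigned to a region. For the same reason the rule for items named in the text reduces to its first part, the 10 widest regions. Other windows and stretches named below were chosen after their values were seen.

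The planned placements over sequenced bases also need the genome. They were replaced by placements over the span from the first to the last listed region of each chromosome, which leaves assembly gaps inside the span in place. For the chromosome test, the expected number followed each chromosome's share of the span. Numbers of regions per chromosome, not positions, were drawn at random 10000 times in proportion to the span, as uniform placement would give. These draws gave a two-sided empirical p, called a permutation p below, with Benjamini-Hochberg adjustment over 20 chromosomes. The smallest unadjusted p they can give is 0.0002. Placed regions are independent of each other, whereas listed regions are not, so windows of 10 Mb (259 windows) and of 5 Mb (512 windows) were also permuted between chromosomes. This second test was chosen after seeing the data. Densities carry 95% exact Poisson intervals and shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. For spacing, 1000 placements kept the number of regions on each chromosome, and the smallest two-sided p is 0.002. Widths were compared between each chromosome and the rest by permuting widths over regions 100000 times, two-sided. Regions of one list are not replicates, so every p describes this list and not the spread between cultures.

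The tests were tried on simulated lists of 9005 regions. Of 1000 chromosomes in 50 uniform lists, 2 were called by the chromosome test. These lists were drawn by the same uniform model as the placements of the test. Its rate of false calls in a patchy list was not tried and is unknown. With chromosome 1 at 1.2 times and X at 0.5 times the uniform density, both were called in 50 of 50 lists. The window permutation called 0 of 200 chromosomes in uniform lists. This trial used fewer permutations than the real test, too few for a single chromosome to pass after adjustment. The 0 calls therefore do not measure its rate of false calls. The window permutation was not tried on patchy lists or on lists with a raised or lowered chromosome, so its power is unknown. The spacing test, scored on the median distance to the nearest region, called 0 of 10 uniform lists. It called 10 of 10 lists in which 20% of regions were placed near another. Those lists were otherwise uniform within each chromosome, so variation of density over 1 Mb or more was not simulated. The counts of dense windows and of neighbours under 1 kb away were not tried on simulated lists. Alternatives were regions at or above the median width of 164 bp, merging of regions within 1 kb, removal of X and the mitochondrial genome, other window sizes, placement from the first base of each chromosome, placement within each region's own 1 Mb window, and removal of windows of 100 kb with 5 or more regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.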

Results

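The study used ChIRP to look for DNA near the long noncoding RNA Meg3 in mouse insulinoma cells. Whether each listed region marks Meg3 RNA was not tested here. The similarity test was planned because probes may capture DNA by direct base pairing and the plasmid carries Meg3 sequence. It was not run. The deposited list for the clone that overexpresses Meg3 held 9010 regions, of which 9005 lay on 20 nuclear chromosomes (19 autosomes and X) and 5 on the mitochondrial genome. No listed region lay on chromosome Y. The list gives positions only. The comparison of the Meg3 clone with the vector clone, and of odd with even probes, therefore could not be measured region by region, and the results below describe where the listed regions lie.

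The nuclear regions were short. Their median width was 164 bp, with quartiles of 112 and 252 bp and extremes of 41 and 962 bp. A width under 100 bp was found for 1706 regions (18.9%), and a width of 500 bp or more for 318 regions (3.53%). No neighbouring regions overlapped. Together the nuclear regions covered 1787 kb, which is 0.0697% of the 2563 Mb between the first and last region of each chromosome.

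The widest regions in the list were mitochondrial. A region of 5072 bp ran from position 4 to 5075 of the mitochondrial genome, the small circular genome carried outside the nucleus, and a region of 4691 bp ran from 11003 to 15693. The other mitochondrial regions lay at 5750 to 6536, 9422 to 9501 and 9789 to 9860. The 5 regions covered 10702 bp, or 68.2% of the 15690 bp from the first to the last of them, against 0.0697% for the nuclear chromosomes. The input library was not analysed here, so this contrast cannot separate capture of Meg3 from copy number or background. The widest nuclear region lay on chromosome 7 from 51761695 to 51762656 (mm9) and spanned 962 bp. It was followed by a region of 945 bp on chromosome 15 (83148222 to 83149166) and a region of 890 bp on chromosome 1 (82551717 to 82552606). Further regions on chromosome 7 spanned 870 bp (86508131 to 86509000) and 849 bp (52748179 to 52749027). The remaining regions among the 10 widest lay on chromosome 4 (47165998 to 47166855, 858 bp), chromosome 1 (54551961 to 54552791, 831 bp) and chromosome 17 (84919474 to 84920301, 828 bp). Their position relative to genes was not analysed here.

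**Figure D1:**
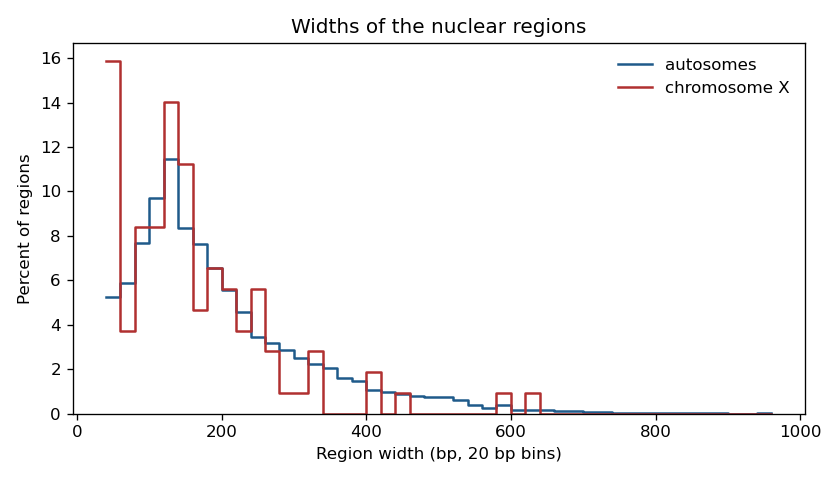
Widths of the nuclear regions in bins of 20 bp (x axis, bp) as a percentage of the regions of each class (y axis), for the autosomes (8898 regions) and chromosome X (107 regions). Both distributions are skewed, with most regions between 41 bp and 462 bp, the 95th percentile of all nuclear regions.

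The next comparison asked whether the regions were spread evenly over the genome. Chromosome 1 carried the highest density, with 1030 regions or 5.32 per Mb (95% exact Poisson interval 5.00 to 5.66), and chromosome X the lowest, with 107 regions or 0.667 per Mb (0.547 to 0.806). Over all nuclear chromosomes the density was 3.51 per Mb. Chromosome 1 held 11.4% of the nuclear regions (95% exact Clopper-Pearson interval 10.8 to 12.1) on 7.55% of the span, 1.52 times the number expected from uniform placement. Chromosome X held 1.19% (0.975 to 1.43) on 6.26% of the span, 0.19 times the expected number.

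Among the other autosomes, density was high on chromosomes 11 (4.93 per Mb, 4.54 to 5.35), 17 (4.50, 4.07 to 4.95), 19 (4.49, 3.96 to 5.07) and 5 (4.46, 4.13 to 4.81). It was low on chromosomes 14 (2.30, 2.04 to 2.59), 18 (2.5, 2.18 to 2.86), 13 (2.75, 2.46 to 3.07), 2 (2.77, 2.53 to 3.03) and 3 (3.03, 2.76 to 3.31). Against uniform placement, 9 chromosomes lay above the expected number, 6 below it and 5 did not pass the test at an adjusted p of 0.05 (two-sided empirical test, Benjamini-Hochberg over 20 chromosomes). The smallest p the placements can give (permutation p = 0.0002, adjusted p = 0.00044) was reached by 9 chromosomes, namely 1, 2, 5, 11, 13, 14, 17, 18 and X.

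Density also varied within chromosomes, by more than independent placement allows. In windows of 10 Mb it was 5.24 ± 2.20 regions per Mb on chromosome 1 (SD over 19 windows), 0.662 ± 0.45 on X (16 windows), 4.96 ± 1.85 on chromosome 11 (12 windows) and 2.31 ± 0.861 on chromosome 14 (12 windows). When whole windows of 10 Mb were permuted between chromosomes, only chromosomes 1 and X of the 20 stood apart (adjusted p = 0.004 for each, permutation test). The corresponding adjusted p was 0.063 for chromosome 11 and 0.065 for chromosome 14. With windows of 5 Mb, chromosomes 11 and 14 passed as well, each at an adjusted p of 0.011. The other chromosomes passed neither permutation, but the power of these permutations was not tried.

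**Figure D2:**
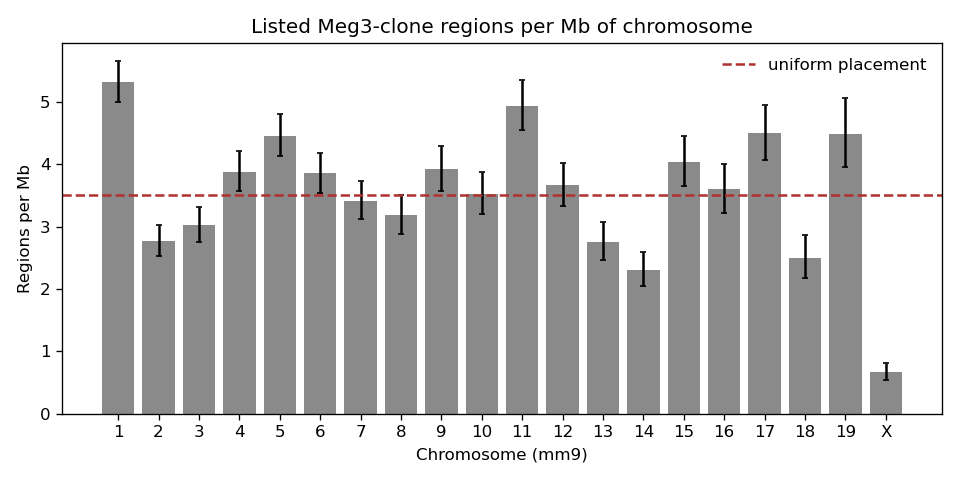
Regions per Mb (y axis) on each nuclear chromosome of mm9 (x axis), with 95% exact Poisson intervals as error bars and the density under uniform placement, 3.51 per Mb, as a dashed line. Chromosome 1 is highest at 5.32 and X lowest at 0.667 regions per Mb.

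**Figure D3:**
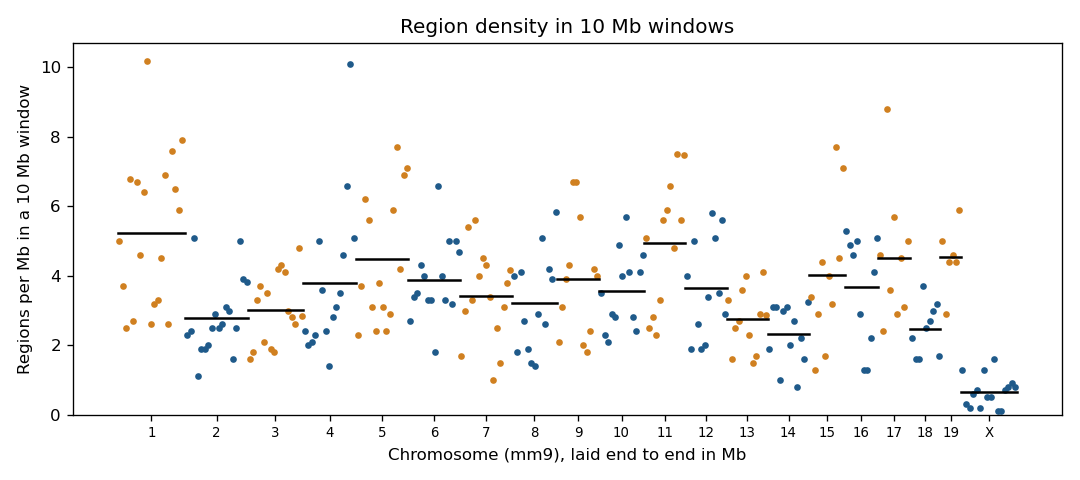
Regions per Mb in each window of 10 Mb (points, y axis) along the chromosomes laid end to end (x axis, Mb; colours alternate between chromosomes), with the mean of each chromosome's windows as a black line. The means are 5.24 on chromosome 1 and 0.662 on X, and windows of one chromosome vary widely.

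Widths differed little between chromosomes. The median was 170 bp on chromosome 1 and 163 bp elsewhere, a difference of 7 bp (95% bootstrap interval -3 to 14). It was 139 bp on X and 164 bp elsewhere, a difference of -25 bp (-42 to -7). The permutation p for X was 0.037 before and 0.72 after adjustment over the 20 chromosomes, and 0 chromosomes passed after adjustment. X was the 1 chromosome with an unadjusted p under 0.05.

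The last comparison asked whether regions lay closer together than chance. The median distance from a region to its nearest neighbour was 73242 bp, against 91847 bp ± 1580 in placements that kept the number per chromosome (mean ± SD over 1000 placements, positions redrawn at random, two-sided permutation p = 0.002, the smallest possible). Windows of 100 kb with 3 or more regions numbered 289, against 171 ± 12 in the placements (permutation p = 0.002). In windows of 1 Mb the direction was the opposite, with 1404 windows of 3 or more regions against 1665 ± 15.3 (permutation p = 0.002). A neighbour less than 1 kb away was found for 156 regions, against 82.2 ± 12.5 (permutation p = 0.002). When each region was instead placed at random within its own 1 Mb window, the first of these comparisons no longer passed (75647 bp ± 1351, permutation p = 0.09) and neither did the second (283 ± 13.3 windows, p = 0.70). The number of regions with a neighbour under 1 kb away remained above those placements (108 ± 14.5, permutation p = 0.004). Among regions at or above the median width alone, placed anywhere on their chromosome, 35 had such a neighbour against 22.6 ± 6.54 (permutation p = 0.068).

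The densest stretch of 100 kb lay on chromosome 11, where 20 regions fell between 3001671 and 3091278. This stretch opens with the first listed region of the chromosome, and whether it holds repeats was not tested. The next was on chromosome 1, with 11 regions between 90113564 and 90155407, followed by a second stretch of chromosome 1 with 6 regions between 85246897 and 85292147. A further 8 windows of 100 kb held 5 regions each. Of these 11 dense windows, 5 were on chromosome 1. At a scale of 1 Mb, the window from 90 to 91 Mb of chromosome 1 held 25 regions, that from 3 to 4 Mb of chromosome 11 held 24, that from 138 to 139 Mb of chromosome 4 held 20, and that from 52 to 53 Mb of chromosome 7 held 19.

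The longest stretches without a region were mostly on X. Of the 95 stretches over 2 Mb, 22 lay on X and together took up 64.3% of its span, against 8.50% of the autosomal span. Uniform placement of the same number of regions on each chromosome gave 59.8% ± 3.89 for X (mean ± SD over 1000 placements, permutation p = 0.25) and 1.09% ± 0.307 for the autosomes (permutation p = 0.002). The longest, 14.3 Mb, ran from 19854252 to 34201743 of X. The longest on an autosome, 7.42 Mb, ran from 39112197 to 46531425 of chromosome 7. Of the 10 longest stretches, 8 were on X. Whether reads can be placed uniquely in these stretches, or whether they hold assembly gaps, was not tested.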

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

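The window permutations, the placement within 1 Mb windows, the placement from the first base and the removal of dense windows, and for spacing also the limit to wider regions and the removal of X, were chosen after seeing the data. The direction and call of chromosome 1 (1.44 to 1.57 times the expected number) and of X (0.15 to 0.19 times) held under every alternative that was run and includes them. Keeping regions at or above the median width left 4510 regions, with 6 chromosomes above the expected number instead of 9 (chromosomes 4, 6 and 9 lost their call) and 6 below. Without X and the mitochondrial genome, 5 chromosomes instead of 9 lay above the expected number, because the expectation for each autosome rises once X is left out. Chromosome 8 gained a call below it there (0.86 times, adjusted permutation p = 0.0042) and without dense windows (0.90 times, adjusted permutation p = 0.048, 7 chromosomes below instead of 6). Permuting windows of 10 Mb left 1 chromosome above and 1 below, and windows of 5 Mb left 2 above and 2 below. Of the 13 other chromosomes that passed against uniform placement, 13 lost their call with 10 Mb windows and 11 with 5 Mb windows. For spacing, placement within 1 Mb windows brought the median distance to 0.97 and the windows with 3 or more regions to 1.02 times the placements, neither past the threshold. Counting in windows of 1 Mb turned the latter to 0.84 times, also past the threshold (permutation p = 0.002). At that size the average of 3.51 regions per Mb already exceeds 3, so that a patchy list fills fewer windows. The excess of regions with a neighbour under 1 kb away fell to 1.55 times with a permutation p of 0.068 among regions at or above the median width. No paired analysis was possible because each group has 1 library and the list holds no value per library. Alternatives that need gene positions, repeat masking, sequence or a value per region were not run. Depth is unknown, so how many sites fell below the threshold of the caller cannot be stated.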

Other observations

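Regions were more frequent towards the end of chromosomes away from the centromere, which in the mouse lies at the start of the numbered sequence. The last 10% of the spans held 1212 regions (13.5%) and the first 10% held 766 (8.51%), where 10% is expected from uniform placement. The last 10% held more than the first 10% on 16 of 20 chromosomes (exact sign test, two-sided p = 0.012), the exceptions being 16, 17, 19 and X. The difference was widest on chromosome 4, with 17.8% against 5.08% of its regions, and on chromosome 5, with 15.9% against 6.19%. This comparison was chosen after the distribution along the chromosomes had been seen. The spans keep assembly gaps in place. Whether gaps, or sequence where reads cannot be placed uniquely, differ between the first and last 10% was not tested.

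Of the tests below, the one that leaves out long stretches without a region had its outcome stated before the result was seen, and the others were chosen after it. Except where stated, density intervals come from resampling windows as if independent, and whether neighbouring windows resemble each other was not measured.

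The excess on chromosome 1 was also seen in its median window, not only in a few dense stretches. The median window of 10 Mb held 1.53 times as many regions as that of the other autosomes (95% bootstrap interval 1.03 to 2.10), which argues against such stretches as the whole cause. The lower quartile of windows was 1.35 times as high (1.05 to 2.08) and the upper quartile 1.5 times (1.19 to 1.77). Chromosome 1 was picked because its density was the highest, and these intervals do not allow for that choice. A candidate explanation, stated as a hypothesis, is that the sequenced clone carries more copies of the whole chromosome, which would raise all windows alike; other properties of the whole chromosome would do the same, and the input library that could decide was not analysed here. A stronger signal per region stays open. The list holds no value of signal, so width was used in its place, and whether width follows signal was not tested. The median width exceeded the rest by 7 bp with an interval from -3 to 14 bp.

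The shortage on chromosome X was deeper than a copy number of 1 against 2 would give if the number of regions followed copies in proportion. The mean window of X held 0.18 times the autosomal density (95% bootstrap interval 0.12 to 0.24), below 0.5. Long stretches without a region are not the whole cause: leaving out all those over 2 Mb can only raise the density on X, and it was then 1.87 regions per Mb against 4.05 on the autosomes treated alike, a ratio of 0.46 (0.38 to 0.58, regions resampled with the gap after each), still below 1. They took up 64.3% of X, against 59.8% ± 3.89 (mean ± SD) in placements of the same number of regions (permutation p = 0.25). The interval of the ratio outside them holds 0.5, so copy number and such stretches acting together were not excluded. Weaker signal on X, with fewer sites passing the threshold of the caller, may contribute and stays open. Width again stood in for signal, which the list does not hold. Regions on X were narrower by a median difference of -25 bp (-42 to -7), but the permutation test did not pass after adjustment. Neither a biological difference of X nor the share of X where reads can be placed uniquely was tested.

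The regions were closely spaced, and the 11 windows of 100 kb with 5 or more regions held only 77 of the 9005 regions. Variation of density over 1 Mb or more is a candidate explanation of the windows of 100 kb with 3 or more regions as a set. These were only 1.02 times as many as under placement within the same 1 Mb. That placement keeps the count of each 1 Mb, also where a tighter cluster raises it. The densest windows were not tested against that placement. In the densest ones of chromosomes 11 and 1, picked for their counts, regions were concentrated within their 1 Mb. On chromosome 11, 20 of the 24 regions from 3 to 4 Mb lay in a window of 100 kb. On chromosome 1, 11 of the 25 regions from 90 to 91 Mb did. Regions with a neighbour under 1 kb away were still 1.44 times as frequent as under placement within the same 1 Mb. Single stretches of signal listed as several regions may account for these. Among regions at or above the median width, placed anywhere on their chromosome, that excess did not pass (1.55 times, permutation p = 0.068). Whether unevenness at 1 Mb follows genes, open chromatin or copy number was not tested here.

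Across the 20 chromosomes, density and median width rose together (Pearson r = 0.68, permutation p = 0.0019, adjusted p = 0.0039; Spearman rho = 0.52, permutation p = 0.02, adjusted p = 0.02; 2 relations computed). Without chromosomes 1 and X, the farthest from the median density, r was 0.35 (permutation p = 0.16) and rho 0.37 (p = 0.13), so that the relation did not pass the test over this narrower range of densities.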
